A study of Mus musculus with 2 samples.

How the data were processed

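Total RNA was extracted from small intestine crypts of 1 wild-type and 1 Eed knockout mouse with a column kit that keeps small RNA, and mRNA libraries were made with the TruSeq RNA kit, version 2, per the labels' protocols. Reads were aligned with TopHat to the mouse build mm9 and values were made with DESeq, per the submitters' processing notes, which give no versions. The counting tool, read length, handling of duplicate reads and strand setting are not given in the sources used here.

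The authors deposited 1 table with 18766 rows, each a RefSeq transcript (17007 coding and 1759 non-coding accessions), and 1 column of normalized signal per library, that is, reads divided by a size factor, per the file headers. The values themselves show the scale: within a tolerance of 1e-06, 100% of the values of each library are whole multiples of that library's lowest value, so whole reads can be recovered. No row is at 1 step in both libraries, while 851 rows are at 1 step in the wild type and 2 in the knockout, 550 at 2 and 1, and 344 at 2 in both. From this it was inferred that 1 read had been added to every value and that rows with no reads were left out, and reads printed here are the recovered steps minus 1. The deposited table also holds the authors' ratio (fold change), its log2 and the authors' p-values, unadjusted and adjusted. The authors' ratio equals the ratio of the 2 columns in every row. How the authors estimated dispersion from 1 library per group is not stated in the sources used here.

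Rows were joined to genes by accession with a RefSeq table of assembly GRCm38.p6, which matched 18510 rows (98.6%). As this is not the authors' build, it served only for names and for which genes neighbour each other, and no coordinates are printed. Symbols are those of the file, except that 30 of 31 symbols that had turned into dates were restored. List members were matched by current symbol first. A gene with several rows is represented by its row with the highest mean, which gave 17216 genes, of which 10879 had a mean of at least 20 normalized reads over the 2 libraries and were tested against the rule. Transcript lengths came from GENCODE vM21 transcripts matched by accession and covered 97.7% of rows.

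The log2 ratio is log2 of the knockout value plus 1 over the wild-type value plus 1, which understates differences of low genes. With 1 library per group there is no test of genotype. A gene was called higher or lower when its log2 ratio was at least 1 in size and its mean at least 20. Ratios printed for genes use recovered reads and size factors, with exact Clopper-Pearson 95% intervals conditional on the sum of both libraries. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where a library had 0 reads, the ratio is a lower bound against a floor of 3 reads in that library. A depth of 6970733 and 5918162 reads means that genes with few reads have wide intervals.

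Each of 35 gene lists, fixed before the data were examined, is described by the median log2 ratio of its members with a mean of at least 20 and, with at least 5 such members, by the percentile of that median among 10000 random lists (seed 1) of the same size matched on mean expression in 20 bins. A percentile describes these 2 libraries and is not a test. Lists outside the central 95% of random lists were taken as standing apart. Named genes were fixed by a rule before the data were examined: the 15 highest and 15 lowest log2 ratios with a mean of at least 100, leaving out predicted genes, up to 4 members per list with the largest ratios, and 21 genes of PRC2, the lineages, stem cells and the cell cycle. Genes named outside this rule are marked where they appear as named after their values were seen.

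Alternatives set before the data were examined were other pseudocounts (0.5 and 10), 4 other scalings, other filters on low values, other thresholds, the mean in place of the median and random lists without matching. Others were chosen after seeing the data: 1 read taken off every value, the sum of a symbol's rows, every row on its own, a correction for an assumed ceiling of 2 reads per base, and an exact binomial test on the recovered reads with Benjamini-Hochberg adjustment at 0.05, which compares these 2 libraries and not the genotypes. The functions were tested on simulated data: for 10879 simulated genes with 200 changed, the rule called 100% of genes changed 3-fold, 8-fold or 20-fold, 6% of those changed 1.5-fold and 15 of 10679 unchanged genes. Intervals held the true ratio for 95.2% of 2000 genes, and 8 of 100 simulated lists of 20 unchanged genes fell outside the central 95%. The simulation drew counting error only (Poisson reads), so these rates leave out differences between animals and between library preparations. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.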

Results

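Bulk RNA-seq was analysed from 2 libraries of small intestine crypts of C57BL/6 mice, 1 wild type and 1 Eed knockout. Crypts are the epithelial pits that hold the stem and progenitor cells of the intestine. Both animals carried AhCre, a Cre recombinase driven by an aryl hydrocarbon receptor responsive promoter, and received 3 injections of β-naphthoflavone, the ligand that switches it on. Crypts were taken 15 days after injection. The knockout animal also carried a floxed Eed gene, which encodes a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates histone H3 at lysine 27. The wild-type library held 6970733 reads assigned to RefSeq transcripts and the knockout library 5918162. With 1 library per genotype there were no replicates, so no difference below has a replicate check and none was tested between genotypes. Genes were called higher or lower by a rule of size, and each ratio carries a 95% interval that covers counting error only. Reads are given as counted, wild type first, and ratios are after scaling by the authors' size factors.

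The comparison asks which crypt transcripts differ when PRC2 function is removed, with the secretory lineages as the focus of the study. Eed itself, the targeted gene (NM_021876), had 588 reads in the wild-type library and 183 in the knockout library, 3.08-fold lower (95% counting interval 2.61 to 3.66). The reads counted cover the whole transcript, and the labels do not say which part of the gene was floxed. Of 9 PRC2 subunits with a mean of at least 20 normalized reads, Eed was the 1 that was at least 2-fold lower and none was 2-fold higher. Suz12, another core subunit, had 27 and 32 reads. Ezh2, the methyltransferase, was under the mean of 20 and so not among the 9, with 25 and 12 reads, a ratio of 0.50 (0.229 to 1.03). The median log2 ratio of the PRC2 list was -0.07, at percentile 57.8 among 10000 random lists of the same size and expression, and its sign turned under each of the other scalings. Of 13 subunits of PRC1, the partner Polycomb complex, 2 were higher: Cbx6 by 2.94-fold (2.55 to 3.39) and Bmi1 by 2.49-fold (2.20 to 2.83). The PRC1 median was 0.15, at percentile 96.7.

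By the rule of size, more genes were higher than lower in the Eed knockout library. Of 10879 genes with a mean of at least 20, 1217 were at least 2-fold higher and 390 at least 2-fold lower on the log2(value + 1) scale. The balance depends on that rule, and may depend on the scaling as well. An exact binomial test on the recovered reads, which compares these 2 libraries and counts small differences, called 2486 higher and 4062 lower. It was chosen after the data were seen and run under the authors' scaling only. Under that scaling the median log2 ratio of genes with a mean of at least 100 was -0.16. How far the excess of lower calls comes from the scaling was not tested. Among abundant, named genes with the highest ratios, Hoxb13, a posterior homeobox gene, had 0 and 803 reads, at least 279-fold higher. Igf2bp1, an RNA-binding protein of fetal tissues, had 0 and 576 reads, at least 200-fold higher. Sim2 was at least 128-fold higher, En2 at least 115-fold and Zic2 at least 82.3-fold. Barx1, a homeobox gene of the embryonic stomach, had 1 and 496 reads, a ratio of 517 (92.4 to 20459). Krt4, a keratin of stratified epithelia, had 1 and 420 reads, and the collagen gene Col14a1 had 2 and 496. Hoxa11os and Foxl2os, with 295 and 263 knockout reads against 0, lie antisense to Hoxa11 and Foxl2, and strand use in the counting is not given in the sources used here.

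At the other end, Trim12a had 443 and 3 reads, a 142-fold lower level (48.2 to 690). Muc5ac, a gel-forming mucin best known from the stomach, had 705 and 8 reads, 84.6-fold lower (42.7 to 197). Akp3, an intestinal alkaline phosphatase, had 1983 and 40 reads, 47.6-fold lower (34.8 to 66.8). Trpa1, an ion channel of enterochromaffin cells, was 25.9-fold lower (12.9 to 60.8), Afp, the fetal albumin gene, 11.6-fold (8.28 to 16.9), and the nucleoside transporter Slc28a1 6.27-fold (5.54 to 7.11). Slc28a1 is among the 200 tested genes around Eed on chromosome 7. Trim30d, 12.1-fold lower (7.24 to 21.5), belongs with Trim12a to a family of closely related copies that lie near Eed on chromosome 7, so the split of reads among them is uncertain.

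In the authors' deposited table, 183 of 18766 transcript rows had an adjusted p below 0.05, 167 higher and 16 lower in the knockout. The authors' deposited table gives Hoxb13 an adjusted p of 7.23e-15, Muc5ac 6.10e-10 and Trim12a 2.16e-08. For Eed the authors' deposited table gives an adjusted p of 0.534. With 1 library per group, the authors' calls compare 2 libraries and cannot measure variation between animals. Most of the higher calls had fewer than 10 wild-type reads. The median log2 ratio of the 10879 genes was -0.11 under the authors' scaling. Scaling to the library totals shifted log2 ratios by up to 0.18, and the share of higher genes among those that differed by at least 2-fold went from 75.7% to 85.9% (1484 higher, 243 lower).

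**Figure D1:**
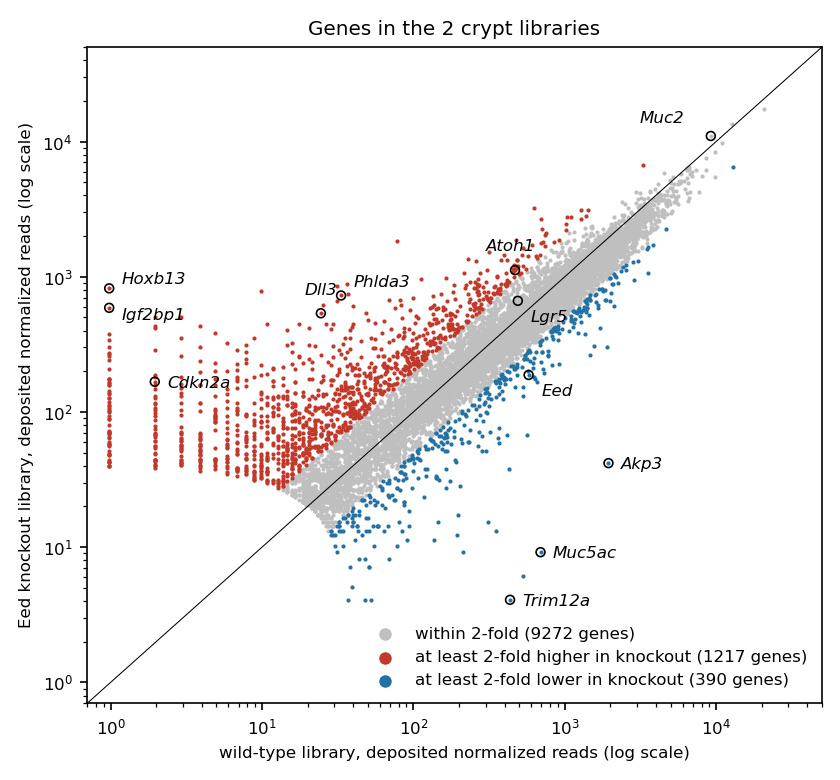
Deposited normalized reads of 10879 genes in the wild-type library (x axis, log scale) and the Eed knockout library (y axis, log scale), 1 point per gene, with the line of equal values. Red points are the 1217 genes at least 2-fold higher and blue points the 390 at least 2-fold lower in the knockout library. Hoxb13 and Igf2bp1 sit at the lower end of the wild-type axis, and Eed, Akp3, Muc5ac and Trim12a lie below the line.

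Developmental transcription factors were higher as a group. All 22 Hox genes with a mean of at least 20 were at least 2-fold higher in the knockout library, and the authors' deposited table called 9 of the list's genes. Most Hox genes had few wild-type reads, so this filter keeps mainly those that were high in the knockout library. Over all 39 with a row, and with genes at 0 wild-type reads set to their bound, 34 were at least 2-fold higher and none lower. Genes with 3 reads or fewer in both libraries, 3 of the 39, were counted as neither. The median log2 ratio of the Hox list was 5.01, above all 10000 random lists. It was 4.57 with the 8 members at 0 wild-type reads set to their bound, and over all 39 genes it was 4.0, again above all random lists (3.84 at bounds). Members from all 4 clusters were among them: Hoxa11 was at least 59.4-fold higher, Hoxb8 at least 29.9-fold, Hoxd13 at least 59.1-fold, and Hoxc6, named after its values were seen, had 1 and 103 reads. Of 46 other developmental transcription factors, 34 were higher and 1 lower, with a median log2 ratio of 4.59 (4.35 with 14 members at their bound), again above all random lists. The filter matters here as well: the median was 2.87 over all 90 with a row (2.18 at bounds), of which 58 were higher and 1 lower at bounds and 16 had 3 reads or fewer in both libraries, and 0.50 over the 17 with a mean of at least 100. Tbx15, a T-box factor of the embryonic skeleton and skin, had 1 and 409 reads, a ratio of 426 (76.1 to 16877). The lower one, Pax8, had 235 and 58 reads, 3.89-fold lower (2.91 to 5.28), and was singled out after its values were seen. The authors' deposited table called 19 of these factors, all higher. Of the intestinal identity factors on the same list, chosen after their values were seen, Cdx2 had 1964 and 1015 reads and Cdx1 1179 and 1066.

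Among 5 inhibitors of cyclin-dependent kinases, Cdkn2a, a locus known to be held silent by Polycomb, was the 1 that differed by at least 2-fold, with 1 and 163 reads and a ratio of 170 (30.1 to 6751). Its neighbour Cdkn2b had 767 and 713 reads, a ratio of 0.969 (0.874 to 1.07), and Cdkn1a had 69 and 72. Cdkn1b had 634 and 394 reads, 1.54-fold lower (1.36 to 1.76). The list's median was -0.05 (percentile 47.0), a sign that turned under the other scalings.

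Goblet cell genes, those of the mucus-secreting lineage, were higher as a group: 10 of 28 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.50, above all 10000 random lists. The lineage regulators Atoh1 and Spdef were 2.39-fold (2.14 to 2.67) and 2.47-fold (2.24 to 2.72) higher. Creb3l1, a transcription factor of secretory cells, was 3.20-fold higher (2.94 to 3.49), and Retnlb, a goblet cell defence protein, had 12 and 127 reads, 11.0-fold higher (6.10 to 21.9). Muc2, the main intestinal mucin, had 9411 and 10766 reads, a ratio of 1.19 (1.16 to 1.23). The lower member was listed under the older symbol Clca1 (today Clca3a1), with 387 and 183 reads, and was named after its values were seen.

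Secretory transcription factors split in direction. Of 21, 6 were higher and 3 lower, with a median of 0.28 at percentile 98.5, a place outside the central 95% that was lost with no filter and with the mean of members. Foxa2 was 3.60-fold higher (2.97 to 4.39), Creb3l4 3.19-fold (2.77 to 3.67) and Bhlha15, a factor of secretory granule maturation, 3.11-fold (2.81 to 3.43). Neurog3, which specifies enteroendocrine cells, was 2.09-fold lower (1.63 to 2.68). The other lower members, Lmx1a (148 and 54 reads) and Rfx6 (32 and 13), also act in that lineage and were named after their values were seen. Gfi1 had 3 and 8 reads, a ratio of 2.78 (0.667 to 16.3), which this depth cannot place.

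Of 32 enteroendocrine genes, 5 were higher and 3 lower, with a median of 0.37 at percentile 99.7. The hormone genes Sct and Pyy were 2.93-fold (2.53 to 3.42) and 2.78-fold (1.88 to 4.20) higher, while the granule protein gene Chga had 1641 and 1550 reads. Pcsk1n and, named after its values were seen, Slc18a1 were also among the higher members. The lower members were Trpa1, Neurog3 and Rfx6. Taking the mean of the members in place of the median, 0.18, put this list at percentile 36.0, inside the spread of its random lists.

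Tuft cell genes, those of the chemosensory lineage, were lower as a group: 6 of 23 were at least 2-fold lower and 1 higher, and the median log2 ratio of -0.75 was below all 10000 random lists. Ly6g6f had 41 and 10 reads, 3.93-fold lower (1.94 to 8.81). Il17rb was 2.37-fold lower (1.57 to 3.64) and Ltc4s, a leukotriene synthase, 2.34-fold (1.55 to 3.60). Trpm5, the taste-type channel, named after its values were seen, had 842 and 390 reads, 2.07-fold lower (1.83 to 2.34). Ptgs1 was 3.08-fold higher (2.42 to 3.95). Dclk1, the usual tuft cell marker, had 1 and 0 reads and gave no ratio. Paneth cell genes, those of the antimicrobial cells at the crypt base, showed no common shift: 4 of 22 were higher and 1 lower, with a median of 0.04 at percentile 91.3. Copz2 was 10.3-fold higher (7.29 to 15.1), Habp2 3.47-fold (3.10 to 3.90) and Sox9 2.12-fold (1.93 to 2.32). Pla2g2a, named after its values were seen, was 2.06-fold higher (1.36 to 3.16). Mptx2 was 2.09-fold lower (1.86 to 2.37), and lysozyme, Lyz1, had 1930 and 1910 reads, at 1.53 and 1.51 reads per base. Defensin genes are near-identical copies, so their reads are uncertain.

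Of 41 enterocyte genes, those of the absorptive cells, 3 were lower and none higher. These were Ace, 3.21-fold lower (2.32 to 4.51), Slc2a2, a glucose transporter, 2.17-fold (2.03 to 2.32), and Treh, 2.28-fold (1.78 to 2.93). The list's median was -0.32, at percentile 11.3. After a correction for an assumed ceiling of 2 reads per base it was -0.60, below all random lists. Alpi had 3803 and 2782 reads and Fabp1 804 and 595. Crypt base stem cell genes had a median of 0.12, at percentile 99.5, with 1 of 18 higher, Sox9, and 1 lower, Scn2b. The mean of this list lay at percentile 69.9, and against random lists without matching its median lay at 94.8. Lgr5, the receptor that marks these cells, was 1.36-fold higher (1.20 to 1.53), while Olfm4 was 1.54-fold lower (1.45 to 1.64), Ascl2 1.49-fold lower (1.19 to 1.87), and Axin2 had 1737 and 1641 reads. Of the 4 members of the reserve stem cell list, Bmi1 was higher and Lrig1, Tert and Mex3a were within 2-fold. None of 25 proliferation genes differed by 2-fold, but 24 of them were below 0, and the median of -0.43 lay at percentile 0.17. The sign alone says little here, as 39 of the 41 enterocyte genes were below 0 too. Mki67 had 4154 and 2551 reads, 1.56-fold lower (1.49 to 1.64).

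Notch pathway genes had a median log2 ratio of 0.47, above all random lists, with 5 of 21 higher and none lower. Dll3, an inhibitory ligand, was 22.8-fold higher (15.2 to 35.9), Notch3 8.95-fold (6.08 to 13.6), Notch4 3.95-fold (3.26 to 4.80) and Jag2 3.59-fold (2.70 to 4.83). The remaining one, Heyl, had 14 and 40 reads and was named after its values were seen. Notch3, Notch4 and Jag2 are also known from vessels, and of 4 endothelial marker genes 2 were higher and 1 lower in the same library. Hes1, the effector that restrains secretory fate, had 376 and 479 reads. Of 20 Wnt targets, 7 were higher and none lower (median 0.40, percentile 99.99), while 13 were within 2-fold and 6 were below 0. The higher ones included Sox17 with 1 and 279 reads, the Wnt inhibitor Notum, 9.48-fold higher (4.93 to 20.4), and Ccnd1, 2.19-fold (2.06 to 2.33). Of 15 p53 targets, 7 were higher and none lower (median 0.82, above all random lists). Phlda3 was 22.5-fold higher (15.8 to 32.9), Plk2 6.00-fold (5.09 to 7.12) and Zmat3 3.92-fold (3.55 to 4.35), while Cdkn1a and, named after its values were seen, Mdm2, with 1105 and 1151 reads, were within 2-fold.

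Targets of the aryl hydrocarbon receptor, which the injected ligand activates, included 3 of 8 that were lower, with a median of -0.60 at percentile 0.25, but the 5 with a mean of at least 100 had a median of -0.28 at percentile 21.6. The lower ones were Ahrr, 3.34-fold lower (2.22 to 5.16), Cyp1a1, 3.05-fold (1.88 to 5.10), and Cyp1b1, 2.02-fold (1.75 to 2.34). Interferon response genes had a median of -0.14 (percentile 24.4), with 3 of 22 higher: Gbp2, Bst2 and Irgm1. This list lay lower, though inside the central 95%, with no filter (-0.26, percentile 3.38) and with a symbol's rows summed (-0.26, percentile 3.7). MHC class II genes had a median of -0.06 (percentile 77.6), and none of 6 differed by 2-fold. The signs of the interferon and MHC class II medians turned under at least 1 other scaling. Endoplasmic reticulum stress genes had a median of 0.07 (percentile 98.9), with 1 of 18 lower, Trib3, by 3.08-fold (2.56 to 3.72). The mean of this list was -0.06, at percentile 41.3, and without matching its median lay at 91.1. Of 9 imprinted genes, 3 were higher and none lower (median 0.82, percentile 97.8): Meg3, at least 26.8-fold, Plagl1, 49.0-fold (22.2 to 135), and Igf2, 5.56-fold (2.97 to 11.3). Over all 15 with a row the median was 0.82, but 0.47 with 0-read genes at their bound, with 4 higher and none lower. The imprinted list fell inside the central 95% under 3 of 4 other scalings and with 1 read taken off every value.

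Transcripts of other tissues were also higher in the Eed knockout library. Of 13 exocrine pancreas genes, 11 were higher and none lower, with a median log2 ratio of 4.37, above all random lists. Prss2, a trypsinogen from a family of near-identical copies, had 2 and 177 reads, Cel, a lipase, 4 and 223, and Cela2a, an elastase, 7 and 242, 36.0-fold higher (17.2 to 90.6). Of 7 fibroblast and muscle genes, 5 were higher (median 3.99, above all random lists): Col1a2, at least 43.1-fold, Col1a1 with 1 and 155 reads, Col3a1 with 6 and 198, Sparc with 4 and 90, and Col6a1 with 3 and 50, named after its values were seen. The filter raises that median: over all 18 members with a row it was 0.82, with 8 higher and none lower. Vim, a filament gene of mesenchymal cells and lymphocytes, also named after its values were seen, had 265 and 210 reads. Of 11 myeloid genes, 5 were higher (median 0.61, percentile 86.8), led by Lyz2, 8.88-fold (5.94 to 13.8), with C1qb, C1qa, Csf1r and, named after its values were seen, Cd14.

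No T or NK cell gene of 11 differed by 2-fold (median -0.08, percentile 26.5, with a sign that turned under the other scalings). Igj and Cd79b, the 2 B and plasma cell genes with a mean of at least 20, were within 2-fold. Of 4 endothelial genes, Plvap and Vwf were higher and Lyve1 was lower, and of 4 enteric neuron and glia genes Ret was higher. Lyve1 is among the 200 tested genes around Eed. Of the red blood cell list 2 of 8 genes had a row, both under a mean of 20, and mitochondrially encoded genes were not analysed here, as none had a row. Both libraries expressed Xist, with 3743 and 4154 reads. Of 9 proximal small intestine genes 2 were higher, Cybrd1 by 11.3-fold (8.40 to 15.4) and Slc40a1 by 2.12-fold (1.93 to 2.33), with a list median of -0.37 (percentile 11.2). Of 9 distal genes 2 were higher, Hoxb13 and the bile acid transporter Slc10a2, 2.63-fold (2.29 to 3.02), with a list median of -0.30 (percentile 16.8). The mean of the distal list was 0.84, opposite in sign, at percentile 99.5. That mean rests on Hoxb13, with a log2 ratio of 8.70, as 6 of the 9 members were below 0. Genes induced by tissue dissociation and stress had a median of -0.52 (percentile 0.01), yet 3 of 16 were higher, Hspb1, Nr4a1 and Egr1, and 4 were lower, Atf3 and, named after their values were seen, Dusp1, Fosb and Hspa1b. The mean of this list was 0.07.

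**Figure D2:**
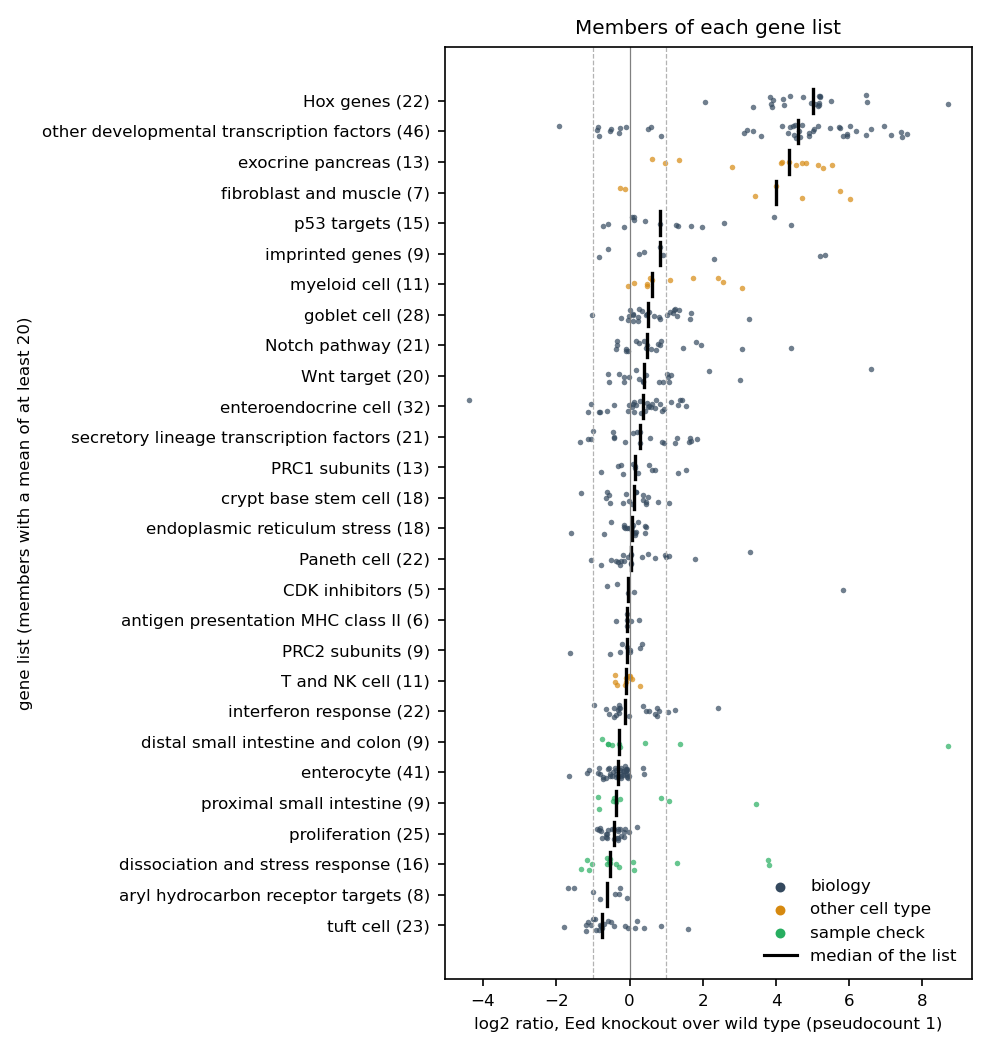
Log2 ratios of the Eed knockout over the wild-type library (x axis, pseudocount 1) for the members of each gene list with at least 5 members at a mean of at least 20 (y axis, number of members in brackets), 1 point per gene, coloured by kind of list. Black bars are list medians and dashed lines mark 2-fold. Hox genes, other developmental transcription factors, exocrine pancreas and fibroblast and muscle genes have medians between 3.99 and 5.01, and tuft cell genes have the lowest median, -0.75.

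Few transcripts had at least 1 read per base in either library. Reads per base of transcript exceeded 2 in 1 of 18334 transcripts in the wild-type library, B4galnt2 with 2.81 (named after its values were seen), and in none in the knockout library, where the highest value was 1.98. In the wild-type library 322 transcripts, and in the knockout library 202, had at least 1 read per base. Lineage markers were among them: Lyz1 with 1.53 and 1.51, Alpi with 1.63 and 1.19 and Fabp1 with 1.45 and 1.08. If a ceiling near 2 acted on the counts, which stays open, their ratios would be understated. Genes with several RefSeq transcripts had a lower median of mean normalized reads, 46.1, than genes with a single one, 115. Low values of genes such as Dclk1, Ezh2 and Gfi1 are read with caution, though whether they lost reads in this way was not tested.

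**Figure D3:**
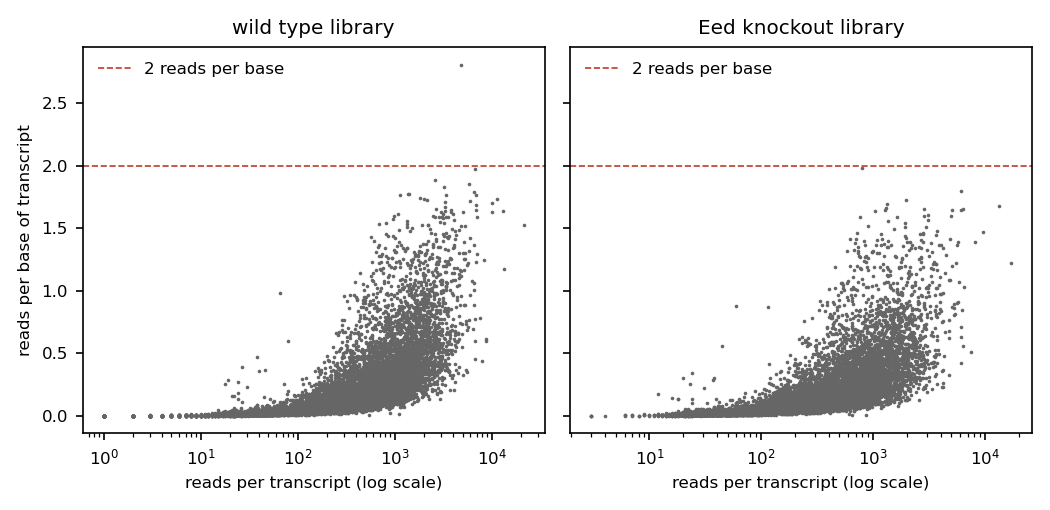
Reads per base of transcript (y axis) against reads per transcript (x axis, log scale) in the wild-type library (left) and the Eed knockout library (right), 1 point per gene with a mean of at least 20. The dashed line marks 2 reads per base, which 1 wild-type gene, at 2.81, exceeds.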

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

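The correction for 2 reads per base, 1 read taken off every value, the sum of rows per symbol, every row on its own and the exact binomial test were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each genotype had 1 library. Of 45 recomputed counts and Eed values, 30 stayed within 1.5 times or within counting error. Of 358 list medians recomputed, 334 kept their place inside or outside the central 95% of random lists, and 23 of these changed sign, all from lists inside it. Of 1458 log2 ratios recomputed for the named genes other than Eed, 1318 stayed within counting error, and none of a gene called by the rule changed sign. Eed kept a log2 ratio between -1.67 and -1.44.

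The number of lower genes, 390, became 243 when scaled to the library total, 252 by the median ratio and 246 without the 50 most abundant rows, since these scalings move ratios up by up to 0.16 to 0.18. With no filter there were 2825 higher and 726 lower genes, and with a mean of at least 100 there were 477 and 247. At 1.5-fold there were 1837 and 1429, and at 4-fold 568 and 59. The exact binomial test on reads called 2486 higher and 4062 lower. At this depth small ratios of abundant genes pass it. It was run under the authors' scaling only, where genes with a mean of at least 100 had a median log2 ratio of -0.16. Whether the turn towards lower calls holds under another scaling was not tested. In the authors' deposited table an unadjusted p below 0.05 was reached by 606 higher and 148 lower rows.

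Under the same 3 scalings the myeloid median was 1.28, 1.27 and 1.28, now above the central 95% with 13 members, and the imprinted median was 0.996, 0.985 and 0.991, no longer past it. The imprinted list also lost its place with 1 read taken off (0.824). The correction for 2 reads per base put the enterocyte (-0.595) and distal (-0.509) medians below the central 95%. With no filter the myeloid list (0.829) passed and the secretory factor list (0.275) did not. At a mean of at least 100 the PRC1 list (0.196) passed and the aryl hydrocarbon receptor list (-0.280, 5 members) did not. With the mean of members, the stem cell (0.0239) and secretory factor (0.319) lists no longer stood apart, and the enterocyte list (-0.377) did. The enteroendocrine (0.184), stress (0.0662) and endoplasmic reticulum stress (-0.0601) lists also stopped standing apart, on the other side of the middle of their random lists, and the distal list (0.841) moved above the central 95%. Without matching, the enterocyte (-0.317) and myeloid (0.608) lists stood apart and the stem cell (0.120) and endoplasmic reticulum stress (0.0730) lists did not. The distal mean rests on Hoxb13, with a log2 ratio of 8.70. The cause of the other shifts was not tested. Few reads limit genes such as Gfi1 and Dclk1.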

Other observations

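The genes in this paragraph and the next were chosen after their values were seen. They were compared with no random lists, so no group shift is read from them. Beside Igf2bp1, the related Igf2bp3 had 37 and 734 reads, 20.7-fold higher (95% counting interval 14.9 to 29.6), and Lin28b had 0 and 97 reads, at least 33.7-fold higher, while Igf2bp2 had 883 and 1149, within 2-fold. Laminin genes, which encode basement membrane chains, went both ways. Lamb1 had 78 and 1814 reads, 24.2-fold higher (19.3 to 30.8), Lamb2 was 8.32-fold (6.29 to 11.2) and Lama5 5.17-fold higher (4.75 to 5.64), while Lama3 was 1.68-fold lower (1.57 to 1.81). Of the signalling genes Wnt4 had 31 and 644 reads and Shh 4 and 90, whereas Ihh, the hedgehog ligand of the adult intestine, had 1245 and 1042 and Bmp2 1187 and 475, 2.40-fold lower (2.15 to 2.67).

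Some genes best known from the stomach had lower values beside Muc5ac: Muc6 by 3.69-fold (3.18 to 4.31), Gkn2 by 4.36-fold (3.32 to 5.81), Gkn1 by 3.26-fold (2.49 to 4.31) and Pgc, a pepsinogen, by 2.70-fold (2.21 to 3.31). Tff2 had 325 and 384 reads. The wild-type library itself held many reads of such genes, 835 for Muc6, 705 for Muc5ac, 374 for Pgc and 291 for Gkn2. A difference in the stretch of gut sampled was not tested. With 1 library per genotype it cannot be told apart from genotype. Lower transporters and detoxifying enzymes were Slc2a7 by 4.12-fold (3.56 to 4.80), Slc5a4a by 4.09-fold (3.67 to 4.56), Slc23a1, a vitamin C transporter, by 3.45-fold (3.15 to 3.78), Cyp2c66 by 6.21-fold (4.78 to 8.20) and Ugt2a3 by 5.57-fold (4.88 to 6.39).

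Of the tests below, those on neighbours of Eed, on the interferon list and on expression in the epithelium were chosen after the results were seen, and the others before, except that the SD of the transcripts between 0.5 and 1 read per base was weighed afterwards. The medians without genes of few reads were added afterwards too. The reading of the duplicate test was made stricter after its values were seen, which left it open, that of the interferon test was changed more than once, and the test without Trim genes replaced the count of all lower genes near Eed.

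Exocrine pancreas and collagen transcripts were higher in the knockout library, and 2 further marker lists were set up to ask whether pancreas or fibroblasts may have been carried over with the crypts. Over 11 further pancreas genes the median log2 ratio was 1.11, but 4 of them had 3 reads or fewer in both libraries, so this median decides nothing; the other 7 had a median of 1.54, with Gp2 at 1 and 30 reads, Sycn at 13 and 66, Ctrl at 28 and 102 and Spink3 at 534 and 433, these 4 named after their values were seen. Over 18 further fibroblast genes with a single RefSeq transcript it was 1.74, between the bounds set beforehand (at least 2 with carry-over, under 1 without), with 12 at least 2-fold higher at bounds and none lower, and 1.85 without the 2 that had 3 reads or fewer in both. Expression in the epithelium after loss of Eed stays open as well. Of the 11 higher pancreas genes, 8 had fewer than 10 wild-type reads. The 5 collagens of the first fibroblast list had a median of 4.70 against 0.62 for its 13 other members, 3 of them higher. That 0.62 is the value of a gene with 0 and 1 reads. Of the list's 18 genes, 5 had 3 reads or fewer in both libraries, so this contrast decides nothing. With 1 library per genotype, carry-over and genotype cannot be told apart. The same limit holds for the higher developmental transcription factors and imprinted genes, for which a share from carried-over cells was not tested. Of the first pancreas list 3 of 14 genes, and of the second 1 of 11, had at least 100 wild-type reads, and no gene of either was on another list.

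Several of the lowest genes lie near Eed on chromosome 7. Of the 200 tested genes around it, 100 on each side, 16 were at least 2-fold lower. Among them were Trim12a, Trim30d, Trim12c, Trim30a and Trim34a (the last 3 named after their values were seen) and, outside the Trim genes, Slc28a1 and Lyve1. The count of 16 was higher than in 97.6% of 6765 overlapping windows of that size, whose median was 7. The highest window held 19, and the highest on other chromosomes 16. Of 59 tested genes at least 4-fold lower, 7 lay in the Eed window, whose 200 genes compare with 10765 tested genes with a place. Of the 15 lowest named genes, 5 lay on chromosome 7, which held 806 of those 10765, and 3 of the 5 lay in the window. The window also held 22 genes at least 2-fold higher, equal to the median window. The count of 16 rests partly on the genes that drew attention to the region, as do the counts of 7 and 5. Without Trim genes and genes over 4-fold lower, the window held 7 lower genes against a median of 6, percentile 63.0. This check leaves out the strongest genes, so it cannot decide whether a segment of another strain was carried with the floxed allele. That explanation stays open, and both animals are C57BL/6 per the labels. For a lower interferon response as the whole cause, none of the 22 listed interferon genes was 2-fold lower and 3 were higher. The listed genes thus did not share a drop of the size seen near Eed. Their median of -0.14 lay above that of the 16 lower genes, -1.80, by more than the SD of the members, 0.792. That gap decides nothing, since the 16 were picked for being at least 2-fold lower. Lower levels of some interferon-induced genes, as seen for Cxcl10 and Trim38 (5.86-fold and 5.71-fold lower), and an effect of Eed loss, which was not tested, stay open.

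A candidate explanation of the near absence of transcripts above 2 reads per base is removal of duplicate reads before counting, which would leave at most 1 read per start position and strand. Among transcripts with 1000 to 4000 reads, the SD of the log2 ratio was 0.284 for 156 with at least 1 read per base and 0.413 for 1131 with under 0.5, a ratio of 0.687, just under the bound of 0.7 set beforehand. The 625 transcripts in between had an SD of 0.435, the highest of the 3, where duplicate removal would put it between the others, so this explanation stays open. No biological explanation of this pattern was tested.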
